A study of Mus musculus with 6 samples.

How the data were processed

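Gene expression was measured on 6 one-colour Agilent mouse arrays, 1 for each combination of 2 genotypes and 3 sorted thymic cell populations. Per the labels, the genotypes were a TNF knockout and a double knockout of TNF and RelA on the C57BL/6 background, and the mice were 1.5 to 2 weeks old. RNA of CD4+CD25hi thymocytes was pooled from 5 mice per genotype, and RNA of CD45-EpCAM+ cells and of CD45+EpCAM- cells from 10 thymi per genotype. The RNA was amplified and labelled with Cy3 by a low-input kit, per the labels' protocols.

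The deposited scanner files hold spot intensity values. Per the file headers, the authors extracted them with Feature Extraction 10.5.1.1 on array design 026655, while the submitters' processing notes name Agilent Feature Extraction 9.5; the headers were followed. The processed signal used here is background-corrected by that software, per the file headers. The deposited value table of the series is on a log2 scale, which no source used here states. Set against the scanner files, it equalled the log2 processed signal minus each array's 75th percentile to within a fixed offset per array of at most 0.0054, with 100.0% of probes within 0.05 after the offset. Its column medians were -3.71, -3.61, -2.84, -2.72, -3.63 and -3.58, in the order CD4+CD25hi, CD45-EpCAM+ and CD45+EpCAM-, TNF knockout first in each.

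Control spots and spots marked as outliers were left out. The main value of a probe was log2 of the processed signal, averaged over its spots, minus the array's 75th percentile over all probes. Of 39429 probes, 39419 were used, and 10 were left out because an array had no usable spot for them. Probes were named through their transcript accessions in a gene table of assembly GRCm38.p6, whereas the array design names build mm9, so that no coordinates are given. A single symbol was found for 27472 probes (69.7%), several for 35 and none for 11912. For 2640 probes the accession differed between versions of the array design. Each of the 20866 genes was represented by its brightest probe, by the mean over the 6 arrays.

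A gene entered a comparison of genotypes within a population if it was well above background on at least 1 of the 2 arrays, by the scanner software's own test. Where it was dim on the other array, that side was set to the higher of its own value and the lowest value among the probes well above background on that array, and the difference is a bound, given as "at least". Genes for which this left no fold were left out: 119 in CD4+CD25hi, 2605 in CD45-EpCAM+ and 27 in CD45+EpCAM-. In the first output these genes were counted at 0; leaving them out was decided after that output had been seen, and medians with them at 0 are among the alternatives. With 1 array per genotype, these differences have no test; genes at least 2-fold apart were counted.

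The genotype effect common to the populations was fitted with limma 3.58.1 in R 4.3.3, with population as a block, over 13743 genes well above background on at least 3 arrays. The fit has 2 residual degrees of freedom and a prior of 1.74. Arrays of a population share a slide, so that the block also removes slide and scan day. Populations were compared with limma with genotype as a covariate, at an adjusted p of 0.05 and at least 2-fold. The p-values were adjusted by the Benjamini-Hochberg method. With 1 array per group, they rest on how far the genotype difference varies between populations. They do not measure the spread between replicate pools.

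Before the data were examined, 25 gene lists were fixed, with 463 entries for 420 different genes, 408 of which were named on the array; some genes stand in several lists. Their names are NF-kB targets, NF-kB pathway components, thymic egress and late maturation, chemokine receptors, chemokines, regulatory T cell, effector regulatory T cell, immediate-early, medullary epithelial, cortical epithelial, tissue-restricted, macrophage, dendritic cell, immature thymocyte, B cell, granulocyte, erythroid, fibroblast and endothelial, interferon-stimulated, MHC class I, MHC class II, proliferation, apoptosis, heat shock and Y-linked genes. Each list's median difference was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, and its percentile describes these arrays only. In the common fit, 24 lists were tested with limma's camera at a preset inter-gene correlation, then with an estimated correlation and with fry.

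The rule for named genes was also fixed then. It takes the 10 largest differences per direction among genes measured on both arrays, bright on the brighter array and with probes in 1 direction. It adds the 5 brightest genes per direction that were dim on 1 array, up to 4 members of each list with the largest differences, cell type markers, and Rela, Tnf, Foxp3, Il2ra, S1pr1, Klf2, Ccr7, Epcam and Aire. Some genes that this rule names are not reported here. For the common effect it takes the 5 genes with the smallest p where fewer than 5 pass.

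The procedures were tested on simulated data. With 100 genes changed 4-fold in all populations, the common fit over 13743 genes recovered 77%, with 5 false calls over both sizes; of 100 changed 2-fold it recovered 6%. The contrast of CD4+CD25hi with CD45-EpCAM+ cells recovered 58% of 4-fold and 1% of 2-fold changes, with 1 false call. Of 100 simulated lists of 15 genes in the CD4+CD25hi pair, 100 shifted by 0.5 and 3 unshifted fell outside the central 95% of random lists. Genes varied independently of each other in these simulations. In the data, genes of a list can vary together, with an estimated correlation of 0.80 for immature thymocyte genes in the common fit. The simulated noise also took the moderated spread of the real fit as the true one. The rates of recovery and of false calls thus need not hold for these data.

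The alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the median of probes detected on every array, the deposited value table, the mean over a gene's probes, other filters on dim probes, an intensity trend in limma and leaving out each array. Normexp had been planned on mean spot signals, which the files used here do not hold, and was run on median spot signals with the median background. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.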

Results

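RelA is the p65 subunit of the transcription factor NF-kB, and mice without it die as embryos unless TNF is also removed, which makes the TNF knockout the control for the double knockout of TNF and RelA. The study asked what RelA does for regulatory T cells that leave the thymus. It profiled CD4+CD25hi thymocytes, a gate enriched in regulatory T cells, and 2 stromal fractions: CD45-EpCAM+ cells, which are thymic epithelial cells, and CD45+EpCAM- cells, a fraction with macrophages and dendritic cells. Each of the 6 groups had 1 array, so that no difference between genotypes within a population has a replicate check. The number of arrays limits the precision. The 75th percentile of the signal was 318 and 272 on the TNF-knockout and double-knockout arrays of CD4+CD25hi thymocytes, 370 and 108 for CD45-EpCAM+ cells, and 633 and 675 for CD45+EpCAM- cells. In the same order, 56.5%, 55.1%, 66.2%, 47.3%, 62.1% and 65.0% of probes were well above background, so that the CD45-EpCAM+ double-knockout array was the dimmest. Differences are log2, double knockout minus TNF knockout, unless stated otherwise.

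Rela was lower in the double knockout in each population. Its level above the array's 75th percentile was 4.52 against 2.66 in CD4+CD25hi thymocytes, a difference of -1.86. It was 3.84 against 1.81 in CD45-EpCAM+ cells, a difference of -2.02, and 4.04 against 3.30 in CD45+EpCAM- cells, a difference of -0.74. Tnf, disrupted in both genotypes, differed by -0.15 in CD4+CD25hi thymocytes and -0.07 in CD45+EpCAM- cells, and was at least 2.32-fold lower in CD45-EpCAM+ cells, where the double-knockout array was not well above background. Each gene was read by 1 probe whose place relative to the disrupted part is not known here, so that residual signal says nothing on protein.

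**Figure D1:**
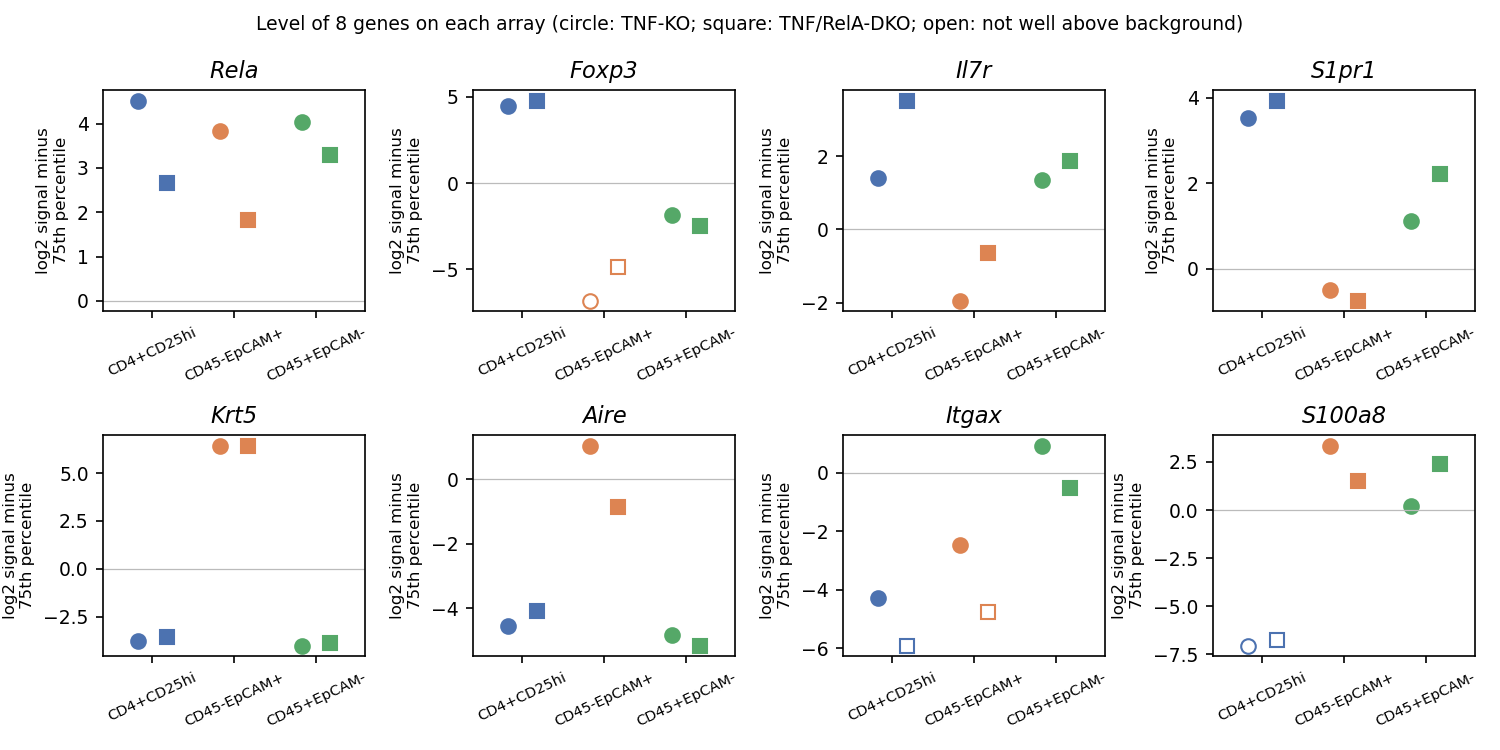
Levels of 8 genes on each of the 6 arrays, as log2 signal minus the array's 75th percentile, by sorted population; circles are the TNF knockout, squares the double knockout, and open symbols were not well above background. Rela was lower in the double knockout in each population, Foxp3 was highest in CD4+CD25hi thymocytes, and Krt5 stood at 6.44 and 6.43 on the CD45-EpCAM+ arrays.

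The sorted populations carried their expected markers. Means and SDs with n = 2 are over the TNF-knockout and the double-knockout array of a population, which are not replicates. Foxp3, the lineage factor of regulatory T cells, had a mean level of 4.63 ± 0.23 (SD, n = 2) in CD4+CD25hi thymocytes and -2.15 ± 0.47 (SD, n = 2) in CD45+EpCAM- cells, a difference of 6.78 (SE 0.69, limma adjusted p = 0.019). It was not well above background in CD45-EpCAM+ cells, so that CD4+CD25hi thymocytes were at least 344-fold higher. Ctla4 and Ikzf2 were 4.86 (SE 0.34) and 5.54 (SE 0.39) higher in CD4+CD25hi thymocytes than in CD45-EpCAM+ cells. Il2ra, which encodes the sorting marker CD25, was 2.46 (SE 0.36) higher there than in CD45-EpCAM+ cells. It was not confined to the thymocytes: its level in CD45-EpCAM+ cells was 3.59, which was 2.76 (SE 0.36) above CD45+EpCAM- cells. In CD45-EpCAM+ cells the keratin Krt8 was at least 1817-fold above CD4+CD25hi thymocytes. Foxn1, the master factor of thymic epithelium, was at least 254-fold above CD4+CD25hi thymocytes and at least 441-fold above CD45+EpCAM- cells, and the thymoproteasome gene Psmb11 at least 132-fold and 229-fold, both outside the limma fit. C1qa and Adgre1, macrophage genes, were at least 55.1-fold and 21.8-fold higher in CD45+EpCAM- cells than in CD4+CD25hi thymocytes. Csf1r, of the same marker group, was less confined, with mean levels of 2.57 in CD45+EpCAM- cells, 1.635 in CD45-EpCAM+ cells and 0.36 in CD4+CD25hi thymocytes.

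T-lineage transcripts were present in every sort. Cd3e, a subunit of the T cell receptor complex, had mean levels of 5.99 ± 0.02 (SD, n = 2) in CD4+CD25hi thymocytes, 4.38 ± 0.69 (SD, n = 2) in CD45-EpCAM+ cells and 5.72 ± 0.07 (SD, n = 2) in CD45+EpCAM- cells. Between CD4+CD25hi thymocytes and CD45+EpCAM- cells Cd3e differed by 0.27 (SE 0.31, limma adjusted p = 0.585) and Cd4 by 0.20 (SE 0.17, limma adjusted p = 0.468). Macrophage transcripts were also present in CD45-EpCAM+ cells. There C1qa was at least 22.1-fold above CD4+CD25hi thymocytes, and Lyz2 had a level of -0.80 against -1.50 in CD45+EpCAM- cells. Between the stromal fractions C1qa (-1.32, SE 0.47, limma adjusted p = 0.0839) and Adgre1 (-0.97, SE 0.38, limma adjusted p = 0.102) did not pass. Ptprc, which encodes CD45, had a level of 0.13 ± 0.83 (SD, n = 2) in CD45-EpCAM+ cells against 3.55 ± 0.16 (SD, n = 2) in CD45+EpCAM- cells.

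By limma, 2511 genes were higher and 2839 lower in CD4+CD25hi thymocytes than in CD45-EpCAM+ cells, 660 higher and 1074 lower than in CD45+EpCAM- cells, and 2665 were higher and 2636 lower in CD45-EpCAM+ than in CD45+EpCAM- cells. The balance of higher and lower genes depended on the scaling: the first split was 1841 to 3236 centred on the median of detected probes and 3057 to 2467 with quantile normalization. The last was 3103 to 1956 with median centring, 3220 to 2163 with normexp and 2337 to 3190 with quantile normalization, and the middle one 639 to 687 with normexp. The median difference of all genes, 0.15, 0.04 and -0.14 in these contrasts, was -0.07, 0.04 and 0.08 with median centring, 0.00, 0.18 and 0.09 with normexp and 0.21, 0.04 and -0.24 with quantile normalization. The 1734 genes between CD4+CD25hi thymocytes and CD45+EpCAM- cells became 0 without any of the 4 arrays of these populations, where the lone array was assumed to vary like the others. Without the TNF-knockout or double-knockout CD4+CD25hi array, 2845 and 3259 genes were called between CD4+CD25hi and CD45-EpCAM+ cells in place of 5350, and without the TNF-knockout or double-knockout CD45+EpCAM- array, 2005 and 2205 between the stromal fractions in place of 5301. Each population lay on its own slide, so that slide and population cannot be told apart.

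In CD4+CD25hi thymocytes the genes that define regulatory T cells stood at like levels in the genotypes, while Il7r was higher and interferon-stimulated genes lower in the double knockout. Foxp3 differed by 0.33 and Il2ra, which encodes CD25, by 0.18, and none of the 25 regulatory T cell genes measured differed 2-fold. Their median was -0.01, its sign turning with quantile normalization or median centring; Ebi3 (0.92), Tigit (-0.77), Socs2 (0.76) and Ctla4 (0.67) differed most. Il7r, the alpha chain of the interleukin 7 receptor, was 4.38-fold higher and the T-box factor gene Eomes 4.02-fold higher. Oasl2, Oas2 and Oas1a, interferon-induced oligoadenylate synthetase genes, were 3.84-fold, 3.32-fold and 2.78-fold lower.

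The genes of thymic egress and late maturation were on balance slightly higher in double-knockout CD4+CD25hi thymocytes. Of 25 measured, 24 lay within 2-fold, with a median of 0.27 at percentile 100 of random lists. S1pr1, the sphingosine 1-phosphate receptor that guides thymocytes out of the thymus, differed by 0.40, its activator Klf2 by 0.39 and Ccr7 by 0.42, while Cd69, which opposes S1pr1 at the cell surface, differed by 0.72 and Ccr9 by -0.53. Among 12 chemokine receptor genes, Cxcr4 (1.57) and Cxcr3 (1.28) were among 3 at least 2-fold higher, with a median of 0.39 at percentile 99.9. Among 8 chemokine genes Xcl1 differed by -1.11, and their median was 0.33 (0.16 with normexp) at percentile 98.5.

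Of 16 effector regulatory T cell genes, Klrg1 (-1.40) and Il1rl1 (-1.40), the gene of the interleukin 33 receptor, were at least 2-fold lower, Maf differed by -0.84 and Cd44 by -0.72, with a list median of -0.33 (-0.16 with normexp) at percentile 0. Of 14 interferon-stimulated genes 3 were at least 2-fold lower, Usp18 (-1.21) among them, with a median of -0.62 at percentile 0. The 21 proliferation genes had a median of -0.57 at percentile 0, with Kif11 at -1.11, Rrm2 at -0.79 and Ccna2 at -0.65. The 18 immature thymocyte genes had a median of -0.26 (-0.14 with normexp) at percentile 0.06, with Ptcra at -1.35, Dntt 2.01-fold lower and Arpp21 at -0.96. NF-kB target genes had a median of -0.05 at percentile 39.8 over 27 genes, which turned to 0.03 with the mean over probes; Vcam1 was at least 3.36-fold lower and Cd40 at least 1.02 (log2) higher. Among 18 NF-kB pathway components Rela alone differed 2-fold, and their median was -0.14 at percentile 4.72.

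The other lists of the CD4+CD25hi pair held few 2-fold differences. The medians were -0.10 for immediate-early genes, with Egr2 and Nr4a3 at -0.97, -0.14 for MHC class I, 0.02 for apoptosis genes, whose sign turned with normexp, and -0.26 for heat shock genes. MHC class II genes had a median of 0.21, with H2-Eb1 at 1.11 and Cd74 at -0.80. These lists of other cell types lay above 0, while immature thymocyte genes lay below: medullary epithelial 0.27, cortical epithelial 0.22, tissue-restricted 0.46, macrophage 0.28, dendritic cell 0.28 (0.16 with normexp or quantile normalization), B cell 0.62 (0.26 with normexp, 0.32 with quantile normalization and 0.39 with genes without a fold at 0), granulocyte 0.45, erythroid 0.35 and fibroblast and endothelial 0.49 (0.26 with normexp). These lists had between 4 and 13 measured genes, and the double-knockout array was the dimmer of the pair. The 2 Y-linked genes measured had a median of 0.47 at percentile 97.9. The labels give no sex for the pooled mice, so that a different share of males is not excluded in any pair.

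In all, 217 genes were at least 2-fold higher and 165 lower of 12936 in CD4+CD25hi thymocytes. Nrn1 (2.22), Mgarp (2.14), Magi1 (2.05), Slc4a2 (1.96), Pde2a (1.89), Ly6d (1.70), Gcg (1.70) and Tent5a (1.62) joined Il7r and Eomes among the largest higher, and Pdzk1ip1 (-2.45), Wnt10a (-2.39), Phldb1 (-1.86), Nrp2 (-1.66), Apol9b (-1.57) and Tmem132a (-1.51) joined Rela and the Oas genes among the lower. Pcolce2, Trnp1, Alpi, Fyb2 and Morc2b were at least 7.22-fold, 6.03-fold, 5.20-fold, 5.18-fold and 5.17-fold higher, and Prox2, Cldn18, Frem3, Olfr1342 and Rgl3 at least 7.86-fold, 8.05-fold, 6.90-fold, 5.68-fold and 4.35-fold lower. With quantile normalization the counts were 148 and 157, so that the larger side turned, with normexp 33 and 18, and with genes well above background on both arrays 125 and 97. Probes of 1 gene differed from each other with an SD of 0.22 in this pair.

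In CD45-EpCAM+ cells, genes of medullary epithelium and genes of other tissues that medullary cells express were lower in the double knockout, while genes of cortical epithelium were not. Of 18 medullary genes 12 were at least 2-fold lower, with a median of -1.43 at percentile 0. Tnfrsf11b, the decoy receptor for RANK ligand, differed by -2.27, Fezf2 by -1.88, Aire, which drives expression of tissue-restricted genes, was 3.73-fold lower, and Skint1 was at least 3.51-fold lower. Of 22 tissue-restricted genes 14 were at least 2-fold lower, with a median of -1.60 (-0.72 with normexp) at percentile 0: Reg3g by -2.52 and Tff3 by -2.50, with Ttr at least 6.87-fold and Sst at least 4.86-fold lower. The 16 cortical genes had a median of 0.43 (0.16 with normexp, 0.25 with quantile normalization) at percentile 99.8, with Ly75 at 1.11, Ctsl at 0.92, Ccl25 at 0.70 and Prss16 at 0.68; Epcam, the sorting marker, differed by -0.63.

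NF-kB target genes were also lower in double-knockout CD45-EpCAM+ cells. Of 31 measured, 13 were at least 2-fold lower and 1 higher, with a median of -0.89 at percentile 0: Ptgs2 (-2.49), Ccl5 (-1.97), Bcl2a1d (-1.96) and Gadd45b (-1.95). Of 19 pathway components 5 were at least 2-fold lower, with a median of -0.34 (-0.64 with normexp) at percentile 0.075. Among these 5 were Rela itself (-2.02), the gene knocked out, Tnfrsf11a (-1.58), which encodes RANK, Relb (-1.15) and Nfkbia (-1.08). Chemokine genes went both ways, 8 of 25 lower and 3 higher, with Ccl4 at 3.05, Ccl24 at 2.08, Ccl5 at -1.97 and Cxcl1 at least 3.71-fold lower, and a median of -0.27 (-0.18 with normexp, -0.43 with quantile normalization) at percentile 0.87. Of 11 chemokine receptor genes 5 were lower and 2 higher, Ccr7 (-1.66) among the lower, with a median of -0.22 (-0.81 with the mean over probes, 0 with genes without a fold at 0).

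Leukocyte transcripts differed in this pair as well. The 18 immature thymocyte genes had a median of 0.78 at percentile 100, with Satb1 at 1.25, Arpp21 at 1.21 and Dntt 2.15-fold higher. Of 10 granulocyte genes 5 were lower, with a median of -1.26 (-0.81 with normexp, -0.59 with genes without a fold at 0) at percentile 0: Mpo by -2.52, Camp by -2.29, S100a9 by -1.86 and S100a8 by -1.82. Fibroblast and endothelial genes had a median of 0.56 at percentile 99.8 (0.24 with the mean over probes or with genes without a fold at 0), with Dcn at 1.31 and Col6a1 at 1.29. Dendritic cell genes had a median of -0.27 (-0.45 with quantile normalization) at percentile 1.45, macrophage genes one between -0.01 and 0 whose sign turned with normexp and quantile normalization, with Lyz1 at -2.35 and Fcgr1 at 1.77, and B cell genes one of 0.24 (0 with genes without a fold at 0). Erythroid genes had a median of -0.60, which turned to positive with normexp and was 0 with genes without a fold at 0, with Hbb-bh1 at least 7.36-fold lower and Hba-a1 at 1.08. The egress list had a median of 0.41 (0.13 with normexp) at percentile 99.95, with Il7r at 1.30, and S1pr1 differed by -0.24.

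MHC class II genes had a median of -0.51 (-0.78 with normexp) at percentile 0.03, with Ciita at 1.62 and Ctss at -1.28, and MHC class I genes one of -0.19 (-0.66 with normexp). The remaining medians of CD45-EpCAM+ cells were 0.19 for regulatory T cell genes, -0.18 for effector regulatory T cell genes, 0.32 for immediate-early (0.12 with normexp), 0.15 for interferon-stimulated, which turned negative with normexp, 0.23 for proliferation, -0.32 for apoptosis (-0.62 with normexp), with Pmaip1 at -1.76 and Fas at -1.56, -0.30 for heat shock (-0.78 with normexp) and -0.05 for Y-linked genes, which turned positive with normexp.

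**Figure D2:**
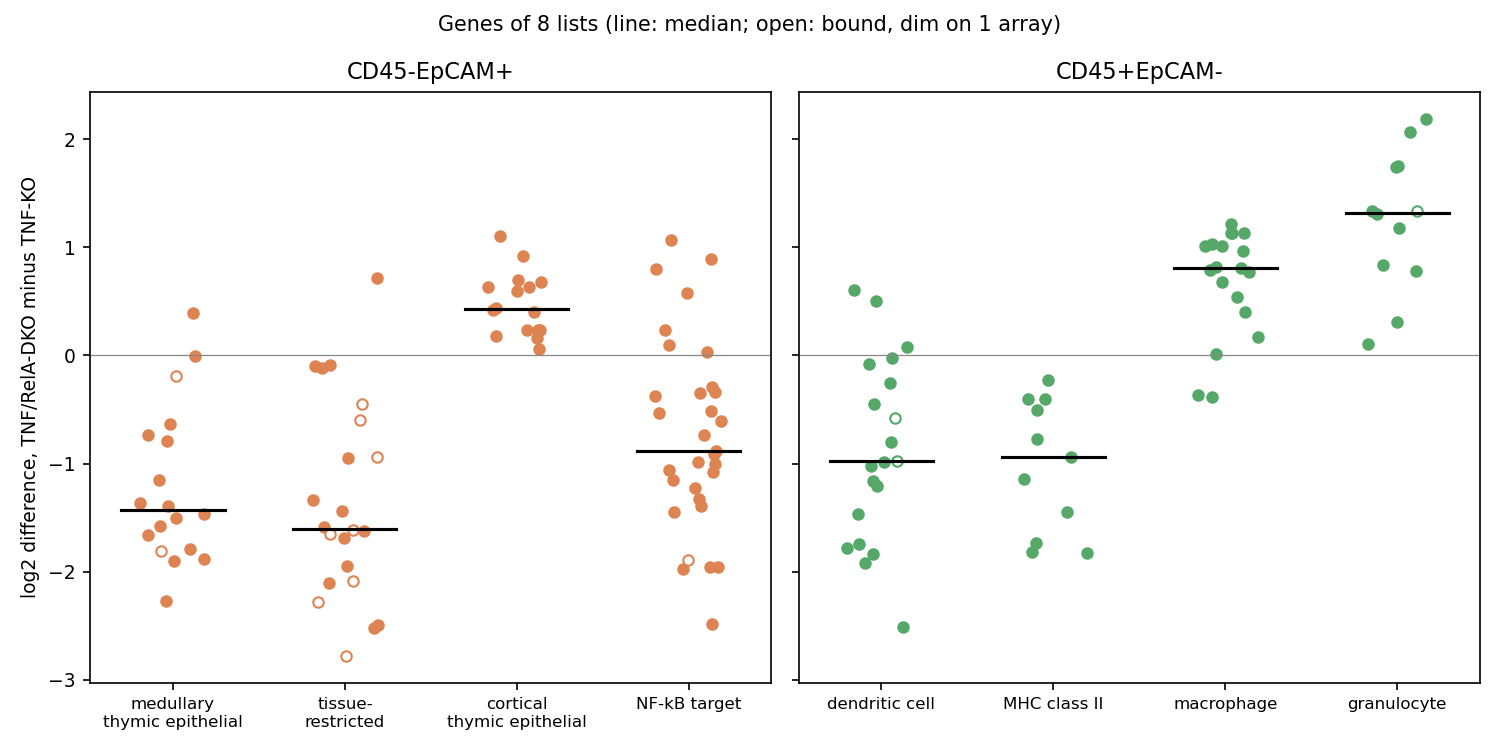
Differences of single genes of 8 lists, as log2 double knockout minus TNF knockout, in CD45-EpCAM+ and CD45+EpCAM- cells; each point is a gene, lines are list medians, and open points are bounds of genes dim on 1 array. Medullary and tissue-restricted medians were -1.43 and -1.60 and the cortical one 0.43, and in CD45+EpCAM- cells the dendritic median was -0.98 and the macrophage one 0.81.

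Among CD45-EpCAM+ cells 673 genes were at least 2-fold higher and 1228 lower of 13208. Cd209f (4.60), Pth (3.74), which encodes parathyroid hormone, Retnla (3.16), Plaur (3.05), Nanog (2.92), Chil3 (2.83), Arg1 (2.64), Thoc2 (2.42, with its other probe at 0.07), Chga (2.25) and Trem1 (2.10) were the largest higher. The acute-phase genes Saa3 (-3.93) and Saa2 (-3.59), Defa29 (-3.77), Hbb-y (-3.33), Klk1b16 (-3.17), Ces2c (-3.11), Aoc1 (-3.06), Oxt (8.02-fold), Smtnl1 (0.92 against -2.08) and Defa23 (-2.87) were the largest lower; members of the Defa and Klk1b families resemble each other so closely that their probes are uncertain. Olfr1265, Pdia2, Hbb-bh2, Olfr361 and Tcl1b1 were at least 23.7-fold, 18.9-fold, 17.8-fold, 17.8-fold and 16.9-fold higher, and Defa42, Defa38, Ces2b, Ces2a and Amph at least 17.1-fold, 20.7-fold, 11.2-fold, 10.1-fold and 8.65-fold lower. These higher bounds rest on the dimmest array. Its floor lay at -2.82, against -4.78 on its partner, which keeps dim genes mainly where they are higher in the double knockout. The lower count was 571 with normexp and 754 with genes well above background on both arrays, and the higher count 447 with a common floor, an alternative chosen after seeing the data. Without a filter on dim genes the counts were 4496 and 2004, so that the larger side turned; probes of 1 gene differed with an SD of 0.33 in this pair.

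In CD45+EpCAM- cells, dendritic cell and MHC class II genes were lower in the double knockout, and macrophage and granulocyte genes higher. Of 20 dendritic genes 9 were at least 2-fold lower and none higher, with a median of -0.98 at percentile 0: Clec10a (-2.51), Cd209a (-1.92), Flt3 (-1.83), the receptor of a dendritic growth factor, and Irf8 (-1.78). Of 11 MHC class II genes 5 were lower, with a median of -0.94 at percentile 0: H2-Ab1 (-1.82), H2-Aa (-1.82), H2-Eb1 (-1.74) and Cd74 (-1.45). Of 19 macrophage genes 7 were higher, with a median of 0.81 at percentile 100: the mannose receptor gene Mrc1 (1.22), Hmox1 (1.14), Mertk (1.13) and Vcam1 (1.13). Of 12 granulocyte genes 8 were higher, with a median of 1.32 (0.70 with normexp) at percentile 100: S100a8 (2.19), S100a9 (2.07), Lcn2 (1.75) and Ngp (1.75).

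Other gene groups shifted beside these. Erythroid genes had a median of 0.61 (0.33 with normexp) at percentile 99.8, with Hba-a1 at 1.64 and Hbb-b2 at least 4.08-fold higher. B cell genes had a median of -0.66 (-0.35 with normexp) at percentile 0, with Fcrla at -2.19. Both Y-linked genes measured were higher, Eif2s3y by 1.58 and Ddx3y by 1.32, with a median of 1.45 at percentile 99.9. A different share of males, not excluded here, bears on every difference of this pair. Immature thymocyte genes had a median of -0.18 at percentile 0.05.

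Of 15 interferon-stimulated genes 7 were lower in double-knockout CD45+EpCAM- cells, with a median of -0.74 at percentile 0: Ifi44 by at least 3.99-fold, Cxcl10 by -1.48, Usp18 by -1.30 and Bst2 by -1.21. NF-kB target genes went both ways, 5 of 30 lower and 4 higher, with Ccl2 at 2.63, Cd40 at -1.84, Cxcl10 at -1.48 and Gadd45b at -1.26, and a median of -0.23 at percentile 0; the 19 pathway components had a median of -0.19 at percentile 0.09, with Nfkb2 at -1.10 and Relb at -0.96. Of 20 chemokine genes 7 were higher and 4 lower, with Ccl7 at 3.18, Ccl8 at 2.77, Ccl2 at 2.63 and Ccl24 at 2.58, and a median of 0.11. Of 27 egress and maturation genes 25 lay within 2-fold, with a median of 0.33 at percentile 100; S1pr1 was 2.14-fold higher, Klf2 differed by 0.86 and Ly6c1 by -1.37.

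The remaining medians of CD45+EpCAM- cells were -0.05 for regulatory T cell genes, with Foxp3 at -0.67, -0.26 for effector regulatory T cell genes (-0.17 with normexp), with Gzmb at -2.29, 0.23 for immediate-early genes, -0.08 for chemokine receptors, with Ccr6 at -1.89, -0.02 for medullary and -0.27 for cortical epithelial genes, 0.001 for tissue-restricted genes, whose sign turned with quantile normalization, 0.17 for fibroblast and endothelial genes, -0.26 for MHC class I, -0.17 for proliferation, -0.07 for apoptosis and -0.16 for heat shock genes (-0.26 with the mean over probes). In all, 265 genes were at least 2-fold higher and 303 lower of 14588. Cstdc4 (3.10), Lpp (3.06, with its other probe at 0.33), Stfa2l1 (2.99), Chil3 (2.89), Stfa1 (2.56), Cstdc5 (2.54) and Gda (5.66-fold) joined Ccl8, Ccl2 and Ccl24 among the largest higher, the Stfa and Cstdc genes being closely alike in sequence. Sct (-4.15), the gene of secretin, Cox6a2 (-3.09), Upb1 (-2.74), Klk1b5 (-2.72), Klk1b26 (-2.66), Klk1 (-2.66), Klk1b27 (-2.54), Ccnd1 (-2.44) and Slc2a6 (-2.43) joined Clec10a among the lower. Arg1, Clec14a, V1rd19, Treh and Pdyn were at least 21.1-fold, 7.67-fold, 6.78-fold, 6.72-fold and 5.27-fold higher, and Calm4, Itgb8, Sema5a, Cdh22 and Havcr1 at least 9.53-fold, 9.53-fold, 7.55-fold, 7.19-fold and 6.61-fold lower. With normexp the counts were 66 and 108, and 174 genes were higher among those well above background on both arrays. Without a filter on dim genes the counts were 850 and 632, so that the larger side turned. Probes of 1 gene differed with an SD of 0.21.

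**Figure D3:**
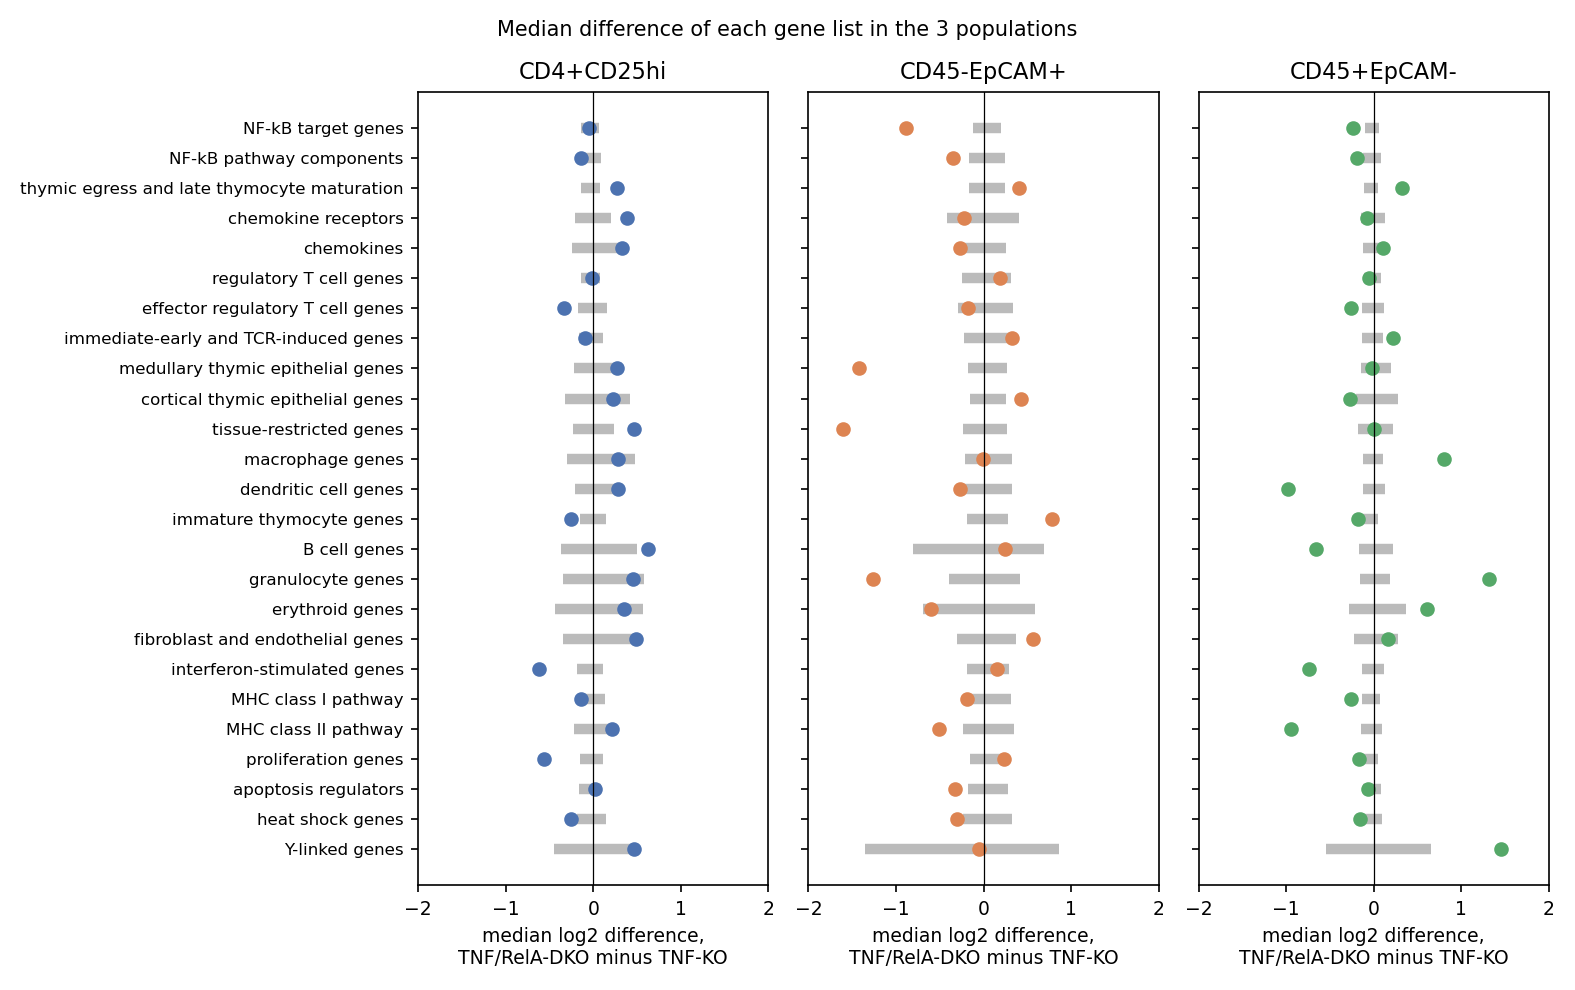
Median difference of each of 25 gene lists, as log2 double knockout minus TNF knockout, in the 3 populations; grey bars span the central 95% of 10000 random lists matched on mean expression. The egress list lay above the bar in each population at 0.27, 0.41 and 0.33, while medullary and tissue-restricted genes lay far below it in CD45-EpCAM+ cells. The egress list holds S1pr1 as well as Cd69, which opposes it, so that its median has no direction of egress. In CD45-EpCAM+ cells S1pr1 and Ccr7 were lower.

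Across the populations, Chil3, a chitinase-like gene of myeloid cells, was higher in the double knockout in 3 of 3 pairs, with a common difference of 2.78 (SE 0.11, limma adjusted p = 0.381). Cd70, a ligand of the TNF family, was lower in 3 of 3 pairs, with a common difference of -2.53 (SE 0.12, limma adjusted p = 0.381), which rests on a dim double-knockout value in CD4+CD25hi thymocytes, where the bound was -1.07. Wnt10a (-2.10, SE 0.16), Txnip (1.35, SE 0.11) and Stra6 (-1.47, SE 0.14) also differed in 1 direction in 3 of 3 pairs, each with a limma adjusted p of 0.679; Stra6 was dim on the CD45+EpCAM- double-knockout array, with a bound of -0.38 in that pair. Rela had a common difference of -1.54 (SE 0.31, limma adjusted p = 0.679). None of these passed: limma called 0 of 13743 genes, with 873 at an unadjusted p under 0.05. At least 2-fold in each population, 10 of 10966 genes were lower, Apol9b, Cd70, Il4i1, Lrrk2, Madcam1, Oasl1, Pde4a, Pdzk1ip1, Tspan33 and Wnt10a, where independent sets would share 0.0602, and 4 were higher, Abca1, Chil3, Fcgr4 and Txnip, against 0.0392. That sharing was counted after the values were seen. Pairs of populations also held more genes apart in opposite directions than independent sets would, so that part of the excess may not depend on direction.

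By camera with limma's fit, 12 of 24 lists passed at the preset correlation, and 0 passed with an estimated correlation or by fry, in either of its forms. With normexp, interferon-stimulated genes passed by mixed fry (adjusted p = 0.013). The egress list was higher (median 0.35, 27 genes, adjusted p = 0.000468, and adjusted p = 0.584 with an estimated correlation), with 9 genes higher and 0 lower at an unadjusted p under 0.05. It mixes genes that further egress with some that oppose it, so that this shift has no direction of egress. Fibroblast and endothelial genes were also higher (median 0.43, adjusted p = 0.0124, and adjusted p = 0.679 with an estimated correlation). NF-kB targets were lower (median -0.34, 30 genes, adjusted p = 0.000468, and adjusted p = 0.695 with an estimated correlation), as were NF-kB pathway components (-0.24, adjusted p = 0.00209, and adjusted p = 0.584 with an estimated correlation) and interferon-stimulated genes (-0.52, adjusted p = 0.000468, and adjusted p = 0.713 with an estimated correlation). The component list holds Rela, the gene knocked out, and was not tested without it. Proliferation genes (-0.16, adjusted p = 0.00167, and adjusted p = 0.713 with an estimated correlation), MHC class I (-0.18, adjusted p = 0.00997, and adjusted p = 0.584 with an estimated correlation) and MHC class II genes (-0.40, adjusted p = 0.0127, and adjusted p = 0.713 with an estimated correlation) were lower. So were effector regulatory T cell genes (-0.09, adjusted p = 0.0113, and adjusted p = 0.584 with an estimated correlation), dendritic cell genes (-0.52, adjusted p = 0.029, and adjusted p = 0.713 with an estimated correlation), medullary epithelial genes (-0.45, adjusted p = 0.0329, and adjusted p = 0.728 with an estimated correlation) and heat shock genes (-0.20, adjusted p = 0.0126, and adjusted p = 0.584 with an estimated correlation). Some of these medians moved with the processing. With normexp they were 0.21 for fibroblast and endothelial, -0.34 for MHC class I, -0.24 for dendritic cell and -0.37 for heat shock genes. The effector regulatory T cell median was -0.29 with quantile normalization.

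Most of these calls were lost when 1 pair was left out, with fewer samples. Without the CD45-EpCAM+ pair the medullary list turned to a median of 0.064 (camera adjusted p = 0.461), and NF-kB targets (-0.17, adjusted p = 0.0794), dendritic cell (-0.38, adjusted p = 0.461) and MHC class II genes (-0.31, adjusted p = 0.096) no longer passed. Without the CD45+EpCAM- pair MHC class II (-0.03, adjusted p = 0.623), dendritic cell (-0.15, adjusted p = 0.406) and MHC class I genes (-0.17, adjusted p = 0.0733) no longer passed. Without the CD4+CD25hi pair, the same held for proliferation (-0.04, adjusted p = 0.474), fibroblast and endothelial (0.35, adjusted p = 0.208) and heat shock genes (-0.20, adjusted p = 0.0573). The egress, NF-kB pathway component, effector regulatory T cell and interferon-stimulated lists passed without any 1 pair at the preset correlation. With an estimated correlation none of these did (adjusted p of 0.638 to 0.824). The component list, with Rela in it, passed only narrowly without the CD45-EpCAM+ pair (camera adjusted p = 0.0466). The interferon-stimulated median was -0.28 without the CD4+CD25hi pair and -0.22 without the CD45+EpCAM- pair, in place of -0.52. The effector regulatory T cell median was -0.34 without the CD45-EpCAM+ pair and -0.16 without the CD45+EpCAM- pair, in place of -0.09. Some medians of lists that lost their call grew when another pair was left out. Proliferation genes stood at -0.39 without the CD45-EpCAM+ pair, in place of -0.16. Without the CD4+CD25hi pair, MHC class II stood at -0.83 in place of -0.40 and medullary genes at -0.72 in place of -0.45.

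Adjusted over the list alone, limma called Usp18 (-1.13, SE 0.13, adjusted p = 0.0221) and Oas1a (-1.12, SE 0.18, adjusted p = 0.0337) among interferon-stimulated genes, lower in 3 of 3 pairs. Without the CD4+CD25hi or the CD45+EpCAM- pair 0 such genes were left, and without the CD45-EpCAM+ pair there were 5. Itgax was called among dendritic cell genes, against 0 over all genes, and 0 in the other lists. Dendritic cell genes called were 3 without the CD4+CD25hi pair, 1 without the CD45-EpCAM+ pair and 0 without the CD45+EpCAM- pair. Itgax was dim on the double-knockout arrays of CD4+CD25hi and CD45-EpCAM+ cells, with bounds of -0.23 and -0.35, so that its call rests on values near background.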

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

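The tests on leukocyte dilution, on loss of RelA and on the CD45+EpCAM- pattern were chosen after these results were seen; the test on the dim array was set down before its result was seen. The results of this part stand out because genes or lists lay in opposite directions in different populations. With 1 array per group, the difference between populations was not tested for any of them.

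Medullary epithelial and tissue-restricted genes were lower in the CD45-EpCAM+ double knockout, with medians of -1.43 and -1.60 (-0.72 for the latter with normexp), while tissue-restricted genes had a median of 0.46 in CD4+CD25hi thymocytes and cortical genes medians of 0.43 (0.16 with normexp) in CD45-EpCAM+ and -0.27 in CD45+EpCAM- cells. The medullary median lay beyond the lower limit of random lists matched on TNF-knockout level, at -1.21 from it. This argues against a loss of signal on the dim double-knockout array that is even among genes of like level. Spike-in controls had median signals of 154 and 163 on the TNF-knockout and double-knockout arrays, while the 75th percentile was 370 and 108. The double-knockout array thus carried less labelled sample RNA, and an uneven loss of single transcripts was not tested. Dilution of epithelial RNA by leukocyte RNA would by itself lower cortical genes too, and their median was 0.43 (0.16 with normexp). That median is part of the pattern that raised the question, so that it adds no separate evidence. Dilution beside a further change stays open, and immature thymocyte genes, at 0.78, went the way that more thymocyte RNA would. Loss of RelA in these cells may lower the genes, and NF-kB targets had a median of -0.89, but with 1 array per genotype it cannot be told apart from any other difference between the samples. Whether the pool held fewer medullary cells, or as many with lower expression, was not tested; Krt5, chosen after its value was seen, differed by -0.01.

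Dendritic cell genes were lower and macrophage and granulocyte genes higher in the CD45+EpCAM- double knockout, with medians of -0.98, 0.81 and 1.32 (0.70 for the last with normexp). Dendritic genes had medians of 0.28 in CD4+CD25hi and -0.27 in CD45-EpCAM+ cells, and granulocyte genes one of -1.26 in CD45-EpCAM+ cells (-0.81 with normexp, -0.59 with genes without a fold at 0). Another share of thymocytes in the sort would by itself move all these lists alike, and the macrophage median lay 1.79 above the dendritic one. These are the medians that raised the question, so that this adds no separate evidence. Another share of thymocytes beside a further change stays open. More blood in the sample may have brought granulocytes, since erythroid genes had a median of 0.61 (0.33 with normexp), and it stays open; whether blood also brought the macrophage genes was not tested. Different shares of the cell types in the pools, from loss of RelA or from the dissection, stay open and untested, with 1 array per genotype.

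Other lists also went in opposite directions. Chemokine genes had medians of 0.33 (0.16 with normexp) in CD4+CD25hi and -0.27 in CD45-EpCAM+ cells. Immature thymocyte genes had medians of 0.78 in CD45-EpCAM+, -0.26 (-0.14 with normexp) in CD4+CD25hi and -0.18 in CD45+EpCAM- cells. B cell genes had medians of 0.62 in CD4+CD25hi (0.26 with normexp, 0.39 with genes without a fold at 0) and -0.66 in CD45+EpCAM- cells (-0.35 with normexp).

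Among single genes, Pde2a differed by 1.89 in CD4+CD25hi, -1.07 in CD45-EpCAM+ and 1.84 in CD45+EpCAM- cells. Between the stromal fractions, CD45-EpCAM+ first, Clec10a differed by 1.80 and -2.51, Cstdc5 by -2.01 and 2.54, Gda by -1.90 and 2.50 and Stfa1 by -1.55 and 2.56. In CD4+CD25hi thymocytes Fyb2 differed by at least 2.37, Ly6d by 1.70 and Gcg by 1.70, against -1.21 and -1.09 for Fyb2 and Ly6d in CD45+EpCAM- cells and -1.62, a bound, for Gcg in CD45-EpCAM+ cells.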

How the results depend on the processing

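Of the alternatives, the common floor, leaving out a population's pair in the gene count of the common effect, and counting genes without a fold at 0 were chosen after seeing the data. Of the 12 lists that passed in the common effect, the medullary one turned direction without the CD45-EpCAM+ pair (median 0.064 in place of -0.45), which rests on fewer samples. No list median within a population that lay outside the central 95% of random lists, and no named gene at least 2-fold apart, turned direction under its alternatives.

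With normexp, genes at least 2-fold higher and lower were 33 and 18 in CD4+CD25hi thymocytes in place of 217 and 165, and 66 and 108 in CD45+EpCAM- cells in place of 265 and 303, while 571 were lower in CD45-EpCAM+ cells in place of 1228; the cause was not tested. Restricted to genes well above background on both arrays, 125 were higher and 97 lower in CD4+CD25hi, 754 lower in CD45-EpCAM+ and 174 higher in CD45+EpCAM- cells, where fewer genes were compared. With no filter and no floor, the counts were 965 and 590, 4496 and 2004, and 850 and 632, in the order CD4+CD25hi, CD45-EpCAM+ and CD45+EpCAM-, with 20866 genes compared. The larger side turned in both stromal fractions. With a common floor, 447 were higher in CD45-EpCAM+ cells in place of 673. The deposited value table equals the main values up to a small offset per array, so that its counts could hardly differ. It left every one of these counts within 1.5 times.

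Between populations, limma with no filter gave 440 genes for CD4+CD25hi against CD45+EpCAM- in place of 1734 and 8826 for CD45-EpCAM+ against CD45+EpCAM- in place of 5301. Leaving out each array in turn gave 2845 to 5862 genes for CD4+CD25hi against CD45-EpCAM+, 0 to 2273 for CD4+CD25hi against CD45+EpCAM- and 2005 to 5830 for CD45-EpCAM+ against CD45+EpCAM-, with the lone array assumed to vary like the others. The common effect had 0 genes by limma under every alternative run, with 873 at an unadjusted p under 0.05 in the reported fit. In place of 12 lists, 0 passed with an estimated correlation, 0 by directional fry and 0 by mixed fry. By camera at the preset correlation, normexp gave 16, quantile normalization 13, median centring 12, and leaving out a pair 11 to 13. Interferon-stimulated genes passed by mixed fry with normexp (adjusted p = 0.013). The balance of higher and lower genes between CD45-EpCAM+ cells and the other populations turned with the scaling.

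Over the alternatives, 389 list medians stayed within their spread and 61 moved, and 1581 values of single genes stayed and 324 moved. The deposited value table, near equal to the main values, is counted among these alternatives and adds to the values that stayed. The cause of the moves was not tested. With genes without a fold counted at 0, medians moved in CD45-EpCAM+ cells for NF-kB targets (-0.61), granulocyte (-0.59), fibroblast and endothelial (0.24), chemokine receptor (0) and erythroid genes (0), and in CD4+CD25hi for B cell genes (0.39). The common fit pairs the genotypes over the populations. Within a population, no paired analysis was possible because each group has 1 array. Signal over background limits what can be seen: the floor lay at -2.82 on the CD45-EpCAM+ double-knockout array and at -4.78 on its TNF-knockout partner.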

Other observations

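The tests on compressed signal and exchanged labels, the splits of the arrays, the scan of gene families and the myeloid genes of this part were chosen after results were seen; the test on RelA-sufficient cells was set down before its result was seen.

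The Rela difference was smaller in CD45+EpCAM- cells (-0.74) than in CD4+CD25hi thymocytes (-1.86) and CD45-EpCAM+ cells (-2.02). The SD of all differences on this pair of arrays was 1.05 times that of the CD4+CD25hi pair, which argues against compressed signal. Labels exchanged within the pair would turn the sign, and the difference was -0.74. This reads the value that raised the question, so that it adds no separate evidence. RelA-sufficient cells in the double-knockout sample may be a source of the signal, but 30 genes at least 2-fold lower in both other populations had a median of -0.66 here, between the values set for and against, so that this cannot be told apart from a smaller effect in these cells.

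With 10 splits of the 6 arrays into 2 groups of 3, a share under 0.05 cannot be reached. The common effect had 0 genes by limma in the real split and at most 0 in the others. At an unadjusted p under 0.05, the real split had 873 genes. The other splits that parted all 3 pairs, as the real one does, had 304, 688 and 359. Splits that parted only the CD45-EpCAM+ pair had 3107, but there the fit reuses the genotype difference of that pair. Those that parted only another pair had 245 and 468.

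Genes at least 2-fold apart were shared between populations more often than independent sets would be: 71 lower in both stromal fractions against 13.5 expected, 34 lower in CD4+CD25hi and CD45-EpCAM+ cells against 6.64, and 28 higher in CD4+CD25hi and CD45+EpCAM- cells against 1.65. Genes lower in CD4+CD25hi and CD45+EpCAM- cells were 20 against 1.365. Genes higher were 21 against 7.17 in both stromal fractions and 21 against 5.77 in CD4+CD25hi and CD45-EpCAM+ cells. Opposite directions were also more frequent, with 56 genes against 19.8 between the stromal fractions. CD4+CD25hi thymocytes had 39 against 12.6 with CD45-EpCAM+ cells and 16 against 3.11 with CD45+EpCAM- cells. Part of the excess thus did not depend on direction. Across all genes measured the differences correlated with r of 0.294 between CD4+CD25hi and CD45+EpCAM- cells, 0.127 between the stromal fractions and 0.0765 between CD4+CD25hi and CD45-EpCAM+ cells.

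Retnla, Chil3 and Arg1, genes known from alternatively activated macrophages and picked from among the largest differences, with no list fixed or tested, were higher in both stromal fractions of the double knockout: Retnla by 3.16 in CD45-EpCAM+ and 2.26 in CD45+EpCAM- cells, Chil3 by 2.83 and 2.89, and Arg1 by 2.64 and at least 21.1-fold. Chil3 differed by 2.62 in CD4+CD25hi thymocytes too, and Cd209f (4.60 and -0.73) and Clec10a (1.80 and -2.51) went apart between the stromal fractions.

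Gene families were scanned for medians beyond all 10000 random lists, and first those are given with a share of at least 0.4 of their genes 2-fold apart in 1 direction. Of 433 families in CD45-EpCAM+ cells, lower ones were Defa (-2.39, 9 of 11 genes at least 2-fold lower), Reg (-2.02, 6 of 6), Fabp (-1.82, 7 of 9), Klk (-1.61, 18 of 22), Cst (-1.37, 4 of 6), Pla (-1.15, 8 of 15), Serpinb (-0.96, 6 of 13) and Krt (-0.89, 18 of 39). Higher families of this pair are not given, since the higher floor of the double-knockout array keeps dim genes mainly where they are higher there. Among 454 families in CD45+EpCAM- cells, Klk was lower (-1.20, 10 of 18) and Klra (0.92, 5 of 10) and Ccl (0.46, 7 of 16) higher, and among 401 in CD4+CD25hi thymocytes Cxcr was higher (0.77, 2 of 5). With a smaller share, Mcm (-0.53), Ifit (-0.60) and Oas (-0.66) lay as far out in CD4+CD25hi thymocytes, and Oas (-0.95), Apol (-0.78), Ly (-0.59), Clec (0.46) and Gimap (0.63) in CD45+EpCAM- cells. The signs of all these families held under each scaling alternative run, where members whose bound turned direction were left out. Members of most of these families share sequence, so that their probes may not tell them apart. With normexp, Pla moved to -0.13, Cst to -0.60 with 0 genes 2-fold lower, Reg to -1.21, Defa to -1.59, Klk in CD45+EpCAM- cells to -0.76, Klra to 0.45, Clec to 0.14, Cxcr to 0.30 and Oas in CD4+CD25hi thymocytes to -0.29. The counts of 2-fold genes fell as well. They were 2 lower and 2 higher of 13 for Pla, 3 lower of 5 for Reg, 1 higher of 10 for Klra and 1 higher of 5 for Cxcr.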
